A study of Homo sapiens with 6 samples.

How the data were processed

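hMeDIP-seq (5hmC) and MeDIP-seq (5mC) libraries were made from A2058 melanoma cells overexpressing wild-type TET2 in high or normal glucose, with 1 library per mark and glucose level and 1 input library per glucose level. Groups were taken from the sample titles. Peak names inside the lists use Ctrl for the high-glucose and Low for the normal-glucose libraries, and the labels were followed. The 2 input libraries were not analysed here as samples. The submitters' processing notes name CASAVA 1.8.2, Bowtie 1.0.0, SAMtools 0.1.18, bedtools 2.17.0 and the build hg19, without giving their roles. The peak caller, its version, the control used and the treatment of duplicate reads are not given in the sources used here. The lists reach position 249240465 on chromosome 1, and all coordinates are given on hg19, the build in those notes, and printed 1-based.

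The authors deposited 1 list of narrow peaks per library, per the labels, and no list of pooled samples was used. For each peak the authors' list gives a display score (the whole part of 10 times the -log10 q column), a fold enrichment over background (a ratio), a -log10 p-value, a -log10 q-value and the summit position. The highest q-value in the deposited lists was 0.0498, 0.0496, 0.0496 and 0.0488 in the high- and normal-glucose 5hmC and the high- and normal-glucose 5mC list, so the lists hold peaks at a q-value of up to 0.05. They held 191394, 210081, 100234 and 91885 peaks. The score column was not used. Fold and p-value were used only to describe, rank or filter peaks within a list and to work out depth.

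Peaks on chromosomes 1 to 22 and X were kept. The 80, 82, 14 and 15 peaks on the Y chromosome and mitochondrial DNA were left out. Rows of a list that overlapped would have been merged, but none did. Regions of 2 lists were called shared when they overlapped by at least 1 bp, counted in NumPy 2.4.6 and pandas 2.3.3 with Python 3.11.15, and bedtools 2.31.1 gave the same numbers. Shares carry Wilson 95% intervals (SciPy 1.17.1), which cover counting only, since reads without molecular identifiers are not independent molecules and regions are not replicates. Chance levels came from 100 random placements of the regions between the outermost listed peaks of their chromosome, which take no account of assembly gaps or mappability. Cover was the percent of each 1 Mb window that lay in peak regions. The main setting, its alternatives and the rule for named regions were fixed before the data were examined. The alternatives were a -log10 p of at least 3, a -log10 q of at least 2, autosomes only, merging of rows within 500 bp, overlap of 50% of both regions, covered length, and equal numbers of top peaks. Alternatives with a -log10 p of at least 10, with matched background, with placement within the same window and with equal totals of cover were added after the data were seen. Alternatives that set a threshold cut every list at it before regions were compared. A region whose partner fell below the threshold then counted as found at 1 glucose level. Thresholds on -log10 p from 3 to 20, and cutoffs on fold enrichment, were looked at before 10 was taken as the added alternative. The ratios of peak region numbers, high over normal glucose, at 3, 5, 7, 10, 15 and 20 are plotted.

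The depth was worked out from the fold and p columns. For 191392 of 191394 peaks of the high-glucose 5hmC list, and for at least 99.99% of peaks in each of the other 3 lists, a whole number of fragments t and an expected count L were found for which the fold equalled (t + 1)/(L + 1) and the p-value was the Poisson probability of more than t, with a misfit in -log10 p under 1% of the step between t and the next whole number. The same search without the 1 added succeeded for 1.3% to 1.85% of 2000 peaks drawn at random per list. The smallest L was 3.03 and 2.64 in the high- and normal-glucose 5hmC lists and 0.737 and 0.615 in the 5mC lists, and was read as the genome-wide background. The shortest peaks, 292, 259, 324 and 325 bp, were also the commonest width in their lists and were read as the fragment length used for calling. Reads per library then follow as background times genome size over fragment length, for an assumed genome of 2700 Mb. These depths are inferred from the values, and no source used here states them. The steps between values of L gave the ratio of library to input reads, and from it the input reads. Ratios of reads within a mark do not depend on the assumed genome size. For matched background, t and L of the library with the larger background were scaled to the smaller background of the pair, and both lists were kept at the same -log10 p. This matches the background and not the read number alone: for 5hmC the background differed by 1.15 times and the reads by 1.02 times, with 33 bp between the fragment lengths, while for 5mC the reads differed by 1.203 times and the fragment lengths by 1 bp. On simulated data of 5000 peaks per mark, the search recovered the count of 100% of peaks, and all overlaps planted among 191314 5hmC and 100220 5mC regions were found.

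With 1 library per group no test between groups was possible and none was run. The named regions are the 10 regions per library with the highest -log10 p among those that overlapped no region of the other glucose level, and the 5 windows of 1 Mb with the largest positive and negative difference in cover per mark. Analyses by gene part and by gene were not made, because no gene annotation on hg19 was used here, and regions carry no gene names for the same reason. Figures were drawn with matplotlib 3.10.9.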

Results

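A2058, a human melanoma cell line, was made to overexpress wild-type TET2, the dioxygenase that oxidises 5-methylcytosine (5mC) to 5-hydroxymethylcytosine (5hmC), and was cultured in high or normal glucose for 7 days. The series addressed how the genomic distribution of both marks differed between the glucose levels. 5hmC was profiled by hMeDIP-seq and 5mC by MeDIP-seq, in which an antibody against the modified base enriches the DNA fragments that carry it before sequencing. The 6 samples were 1 5hmC, 1 5mC and 1 input library at each glucose level, and the 4 immunoprecipitated libraries were analysed through their deposited peak lists on hg19. With 1 library per group, no comparison has a replicate check, no p-value is given across regions, and the intervals and chance levels describe these libraries only. The lists carry no read numbers, but the fold and p columns allowed the depth to be worked out. It came to 28.0 M reads for the high-glucose and 27.5 M for the normal-glucose 5hmC library, and to 6.14 M and 5.11 M for the 5mC libraries, if the caller assumed a genome of 2700 Mb. The 5mC lists therefore rest on fewer reads than the 5hmC lists, and the high-glucose 5mC library on 1.203 times as many as its normal-glucose counterpart. Regions are given by position only, because no gene annotation on hg19 was used here.

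On chromosomes 1 to 22 and X, fewer 5hmC peak regions were listed in high glucose than in normal glucose, 191314 against 209999, a ratio of 0.911. They covered 115.0 Mb in high glucose and 124.8 Mb in normal glucose, with mean widths of 601 and 594 bp. The ratio was below 1 on 23 of 23 chromosomes. It was lowest on chromosome 22, at 0.847, on chromosome 21, at 0.856, and on chromosome 17, at 0.868, and highest on the X chromosome, at 0.967. With only peaks of -log10 p of at least 10 the order turned, with 95542 regions in high and 85278 in normal glucose, a ratio of 1.12 that was above 1 on 23 of 23 chromosomes. The smallest expected count, read as the background, was 3.03 in the high-glucose and 2.64 in the normal-glucose 5hmC list. After the high-glucose list was scaled to the lower background, a step chosen like the stricter thresholds after the data were seen, the ratio was 0.907 at the threshold of the lists, 0.941 at a -log10 p of at least 10 and 1.06 at 20. At the threshold of the lists the scaling left 190402 of the 191314 high-glucose regions, so the ratio there could hardly change.

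**Figure D1:**
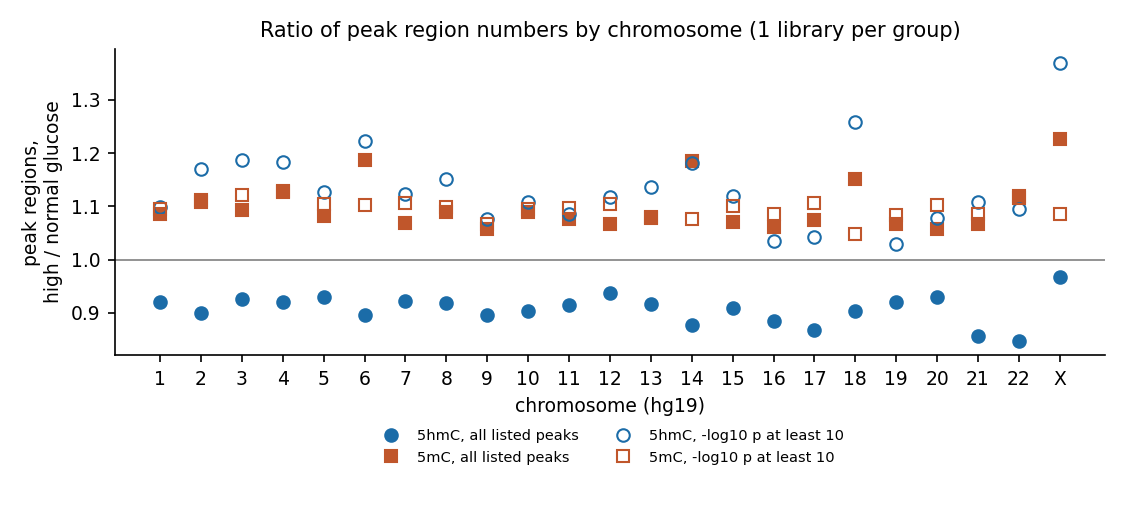
Number of peak regions in high glucose divided by that in normal glucose (vertical axis) for each chromosome (horizontal axis), for 5hmC (circles) and 5mC (squares), over all listed peaks (filled) and over peaks with -log10 p of at least 10 (open), 1 library per group. Over all listed peaks the 5hmC ratio lies below 1 and the 5mC ratio above 1 on 23 of 23 chromosomes, and the 5hmC ratio lies above 1 on 23 of 23 at the stricter threshold.

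The 5mC lists differed in the other direction. High glucose had 100220 5mC peak regions and normal glucose 91870, a ratio of 1.09 that was above 1 on 23 of 23 chromosomes. They covered 71.4 Mb and 66.2 Mb, with mean widths of 712 and 721 bp. The ratio was highest on the X chromosome, at 1.23, on chromosome 6, at 1.19, and on chromosome 14, at 1.19, and lowest on chromosomes 9 and 20, at 1.06. With only peaks of -log10 p of at least 10 it was 1.097, again above 1 on 23 of 23 chromosomes. The high-glucose library was also the deeper of the pair. After it was scaled to the background of the normal-glucose library, the ratio was 1.09 at the threshold of the lists and 0.953 at a -log10 p of at least 10. At the threshold of the lists the scaling left 99717 of the 100220 high-glucose regions, so the ratio there could hardly change.

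**Figure D2:**
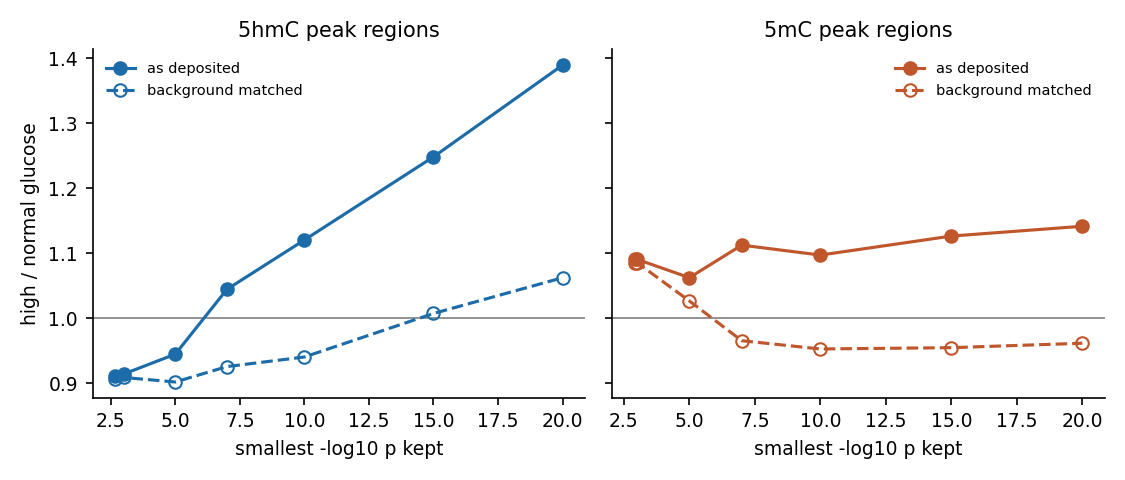
Number of peak regions in high glucose divided by that in normal glucose (vertical axis) against the smallest -log10 p kept (horizontal axis), for 5hmC (left) and 5mC (right), with the lists as deposited (solid) and with the list of larger background scaled down (dashed). The deposited 5hmC ratio goes from 0.911 to 1.39 and the background-matched one from 0.907 to 1.06, while the background-matched 5mC ratio goes from 1.09 to 0.962.

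Most peak regions of either mark were found at both glucose levels. Of the 5hmC regions in high glucose, 145283 of 191314 overlapped a normal-glucose region by at least 1 bp, or 75.9% (Wilson 95% interval 75.7 to 76.1), and 68.8% of the normal-glucose regions overlapped a high-glucose region (68.6 to 69.0). Random placement of the high-glucose regions on their chromosomes gave 9.48%, and at most 9.65% in 100 placements. For 5mC, 71.7% of high-glucose regions (71.4 to 72.0) and 78.5% of normal-glucose regions (78.2 to 78.7) were shared, where random placement gave 5.76% and 6.27%. Regions found at 1 glucose level were weaker and narrower than shared ones. In the high-glucose 5hmC list their median -log10 p was 7.25 against 11.6 for shared regions, and their median width 352 bp against 518 bp. In the normal-glucose 5hmC list the medians were 6.31 against 10.6, in the high-glucose 5mC list 6.78 against 14.2 and in the normal-glucose 5mC list 6.53 against 12.7. Among regions with a -log10 p of at least 20, the share with no partner was 0.776% of 30791 in the high-glucose and 0.559% of 22165 in the normal-glucose 5hmC list, and 0.320% of 24974 and 0.0960% of 21879 in the 5mC lists.

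Ranked by -log10 p, the strongest 5hmC region found in high glucose alone lay on chromosome 17 from 14232505 to 14233039, with a fold enrichment of 10.6 and a -log10 p of 33.9, 3009 bp from the nearest normal-glucose region. It was followed by chromosome 12 from 86531717 to 86532181, with a fold of 10.7 and no normal-glucose region within 44034 bp, and chromosome 21 from 44057244 to 44057757, with a fold of 9.30, where 5mC was listed at both glucose levels. The other 7 of the 10 strongest lay on chromosome 3 (106748640 to 106749117), chromosome 1 (63482311 to 63482765), chromosome 5 (94603325 to 94603775), chromosome 12 (66523484 to 66524095), chromosome 6 (124144371 to 124145020), chromosome 9 (36929061 to 36929481) and chromosome 8 (62124900 to 62125473). Among these 10 regions, 1 overlapped a 5mC region. The strongest 5hmC region found in normal glucose alone lay on chromosome 2 from 55600253 to 55600702, with a fold of 10.6 and a -log10 p of 33.8. Next came chromosome 4 from 3232770 to 3233335, with a fold of 9.58, 298 bp from the nearest high-glucose region. 5mC was listed there in normal glucose only. Chromosome 16 from 51796416 to 51797274, with a fold of 10.4, followed, 729 bp from the nearest high-glucose region. The other 7 of normal glucose lay on chromosome 9 (132224658 to 132225116), chromosome 19 (14705117 to 14705455), chromosome 9 (19120824 to 19121955), chromosome 20 (47886677 to 47887603), chromosome 1 (201267839 to 201268469), chromosome 10 (115416610 to 115417106) and chromosome 11 (92959593 to 92959987). Of these 10 regions, 3 overlapped a 5mC region. The summits of the 10 high-glucose regions held 40 to 47 fragments and those of the 10 normal-glucose regions 35 to 44. The nearest 5hmC region of the other glucose level lay 569 to 44034 bp from the high-glucose and 298 to 6851 bp from the normal-glucose regions. All folds and p-values are those of the authors' peak lists, and a region found at 1 glucose level is not thereby shown to differ.

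The strongest 5mC region found in high glucose alone lay on the X chromosome from 71767665 to 71768156, with a fold of 17.8 and a -log10 p of 38.3. It overlapped a 5hmC region of high glucose and none of normal glucose, and the nearest normal-glucose 5mC region was 21899 bp away. It was followed by chromosome 11 from 64669363 to 64670557, with a fold of 14.6, where 5hmC was listed at both glucose levels, and chromosome 1 from 197318963 to 197319474, with a fold of 13.1. The other 7 lay on chromosome 2 (236799579 to 236800507), chromosome 11 (126448140 to 126448760), chromosome 9 (106877418 to 106877994), chromosome 17 (77846570 to 77847066), chromosome 10 (104444841 to 104445840), chromosome 5 (165723759 to 165724264) and chromosome 19 (3721949 to 3722380). In normal glucose alone, the strongest 5mC region lay on chromosome 10 from 79570595 to 79571065, with a fold of 14.4 and a -log10 p of 29.4, and overlapped a 5hmC region of high glucose only. Chromosome 1 from 54952832 to 54953505, with a fold of 14.9 and 5hmC at both glucose levels, and chromosome 7 from 134872801 to 134873447, with a fold of 13.9, came next. The other 7 of normal glucose lay on chromosome 1 (229412863 to 229413329), chromosome 4 (185349897 to 185350325), chromosome 13 (106694798 to 106695326), chromosome 3 (52577933 to 52578398), chromosome 19 (3925249 to 3925737), chromosome 11 (33424690 to 33425224) and chromosome 9 (112177306 to 112178281). Of the 10 strongest regions, 3 of those in high glucose alone and 6 of those in normal glucose alone overlapped a 5hmC region. Over all 5mC regions of 1 glucose level the shares were closer, 25.4% of 28343 in high and 28.8% of 19789 in normal glucose. The summits of the 10 strongest held 22 to 30 fragments in high and 20 to 25 in normal glucose. The nearest 5mC region of the other glucose level lay 387 to 84626 bp from the high-glucose and 504 to 12319 bp from the normal-glucose regions.

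The 5 windows of 1 Mb with the largest 5hmC deficit in high glucose were rich in 5mC. Windows were ranked by the absolute difference in cover, and a deficit can be large only where 5hmC cover is large. The median window had a 5hmC cover of 2.91% at each glucose level. Since 5hmC and 5mC cover rose together across windows (Spearman rho 0.802 in high and 0.845 in normal glucose), richness in 5mC follows in part from this ranking. The largest difference was on chromosome 17 from 79000001 to 80000000, where 5hmC regions covered 22.8% in high and 32.0% in normal glucose, while 5mC covered 39.2% and 37.6%. Next were chromosome 9 from 139000001 to 140000000, with 20.5% and 27.8% covered by 5hmC, chromosome 1 from 1000001 to 2000000, with 20.5% and 27.3%, chromosome 16 from 1 to 1000000, with 18.2% and 24.6%, and chromosome 1 from 6000001 to 7000000, with 17.5% and 23.7%. The 5mC cover of these 5 windows ranged from 16.8% to 39.2%. The 5 windows with the largest 5hmC excess in high glucose had a 5mC cover under 1% in each list. The median window had 1.01% in high and 0.901% in normal glucose, so these windows were below the median but not all far below it. The window of chromosome 1 from 18000001 had 0.979% and 0.716%. They lay on chromosome 1 from 37000001 (9.51% and 8.09% covered by 5hmC in high and normal glucose), 34000001 (7.73% and 6.34%), 18000001 (7.84% and 6.54%) and 176000001 (4.58% and 3.36%), and on chromosome 17 from 32000001 (5.502% and 4.17%). Of 2875 windows, 5hmC cover was lower in high glucose in 1517 and higher in 1350. The 10 windows named here kept their direction with only peaks of -log10 p of at least 10, although at that threshold 5hmC cover was lower in high glucose in 708 windows and higher in 2150.

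**Figure D3:**
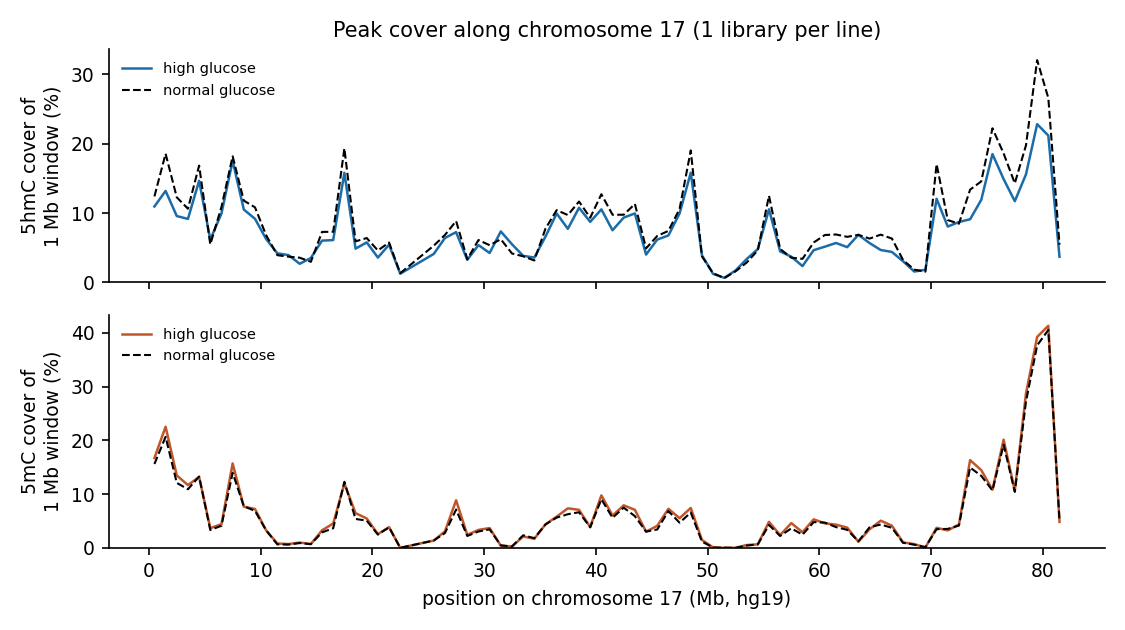
Percent of each 1 Mb window covered by peak regions (vertical axes) along chromosome 17 on hg19 (horizontal axis, Mb), for 5hmC (top) and 5mC (bottom) in high (solid) and normal glucose (dashed), 1 library per line. In the window from 79000001 to 80000000, 5hmC covers 22.8% in high and 32.0% in normal glucose, where 5mC covers 39.2% and 37.6%.

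5mC cover was higher in high glucose in 2089 of the 2875 windows and lower in 689. The largest excess was on chromosome 19 from 1000001 to 2000000, with 35.4% in high and 32.1% in normal glucose. Chromosome 19 from 2000001 (29.3% and 26.8%), chromosome 7 from 1 (34.7% and 32.3%), chromosome 16 from 89000001 (31.8% and 29.5%) and chromosome 9 from 139000001 (34.1% and 32.0%) followed. 5hmC cover was lower in high glucose in each of these 5 windows, for example 17.9% against 23.7% in the window of chromosome 16. They were rich in 5mC. With all windows split into 5 equal groups by 5mC cover, 5hmC cover was lower in high glucose in 92.5% of the richest group. The largest deficits of 5mC were under 1 percentage point and lay on chromosome 16 from 23000001 (2.65% and 3.32%) and 85000001 (22.7% and 23.3%), on chromosome 2 from 86000001 (2.83% and 3.47%), on chromosome 9 from 138000001 (11.1% and 11.7%) and on chromosome 11 from 117000001 (3.54% and 4.10%). With only peaks of -log10 p of at least 10, 4 of these 5 deficits kept their direction. 5hmC cover went both ways in the deficit windows. It was lower in high glucose on chromosome 16 from 85000001 (19.4% and 24.6%), chromosome 2 (4.95% and 6.07%) and chromosome 9 (11.9% and 13.3%). It was higher on chromosome 16 from 23000001 (5.98% and 5.22%) and chromosome 11 (8.81% and 8.46%).

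A smaller share of 5mC regions carried 5hmC in high glucose. Of the high-glucose 5mC regions, 32.2% (Wilson 95% interval 31.9 to 32.5) overlapped a high-glucose 5hmC region, against 39.7% (39.3 to 40.0) of normal-glucose 5mC regions with normal-glucose 5hmC, a difference of -7.49 percentage points. Random placement gave 9.81% and 10.9%, and random placement within the same 1 Mb window, an alternative added after the data were seen, gave 15.8% and 18.6%. As a share, the difference followed the 5hmC library more than the 5mC library. The high-glucose 5mC regions overlapped the normal-glucose 5hmC regions at 37.2%, and the normal-glucose 5mC regions overlapped the high-glucose 5hmC regions at 33.4%. Placement within the same window gave 18.2% and 16.2% for these. Divided by that placement, the shares were close, at 2.03 within high and 2.13 within normal glucose, and 2.05 and 2.06 across the glucose levels. On this ratio scale little of the difference was left. In percentage points the placements within high and within normal glucose, 15.8% and 18.6%, lay closer together than the shares, 32.2% and 39.7%. Among 5hmC regions found in high glucose alone, 4807 of 46031 overlapped a 5mC region of either list, or 10.4% (10.2 to 10.7), against 11587 of 65554, or 17.7% (17.4 to 17.97), of those found in normal glucose alone. Shared 5hmC regions overlapped 5mC at 22.9% in the high-glucose and 22.7% in the normal-glucose list. For 5hmC regions of 1 glucose level with a -log10 p of at least 10, the shares were 6.97% in high and 16.6% in normal glucose. These regions were still set against the full lists. No random placement was made for these shares of 5hmC regions, so the 5mC density of the windows where they lie is not taken into account. The difference in the share of 5mC regions with 5hmC was -3.54 percentage points when the same number of top peaks was taken from each library, -3.33 at a -log10 p of at least 10 and -3.15 when 50% of both regions had to overlap.

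**Figure D4:**
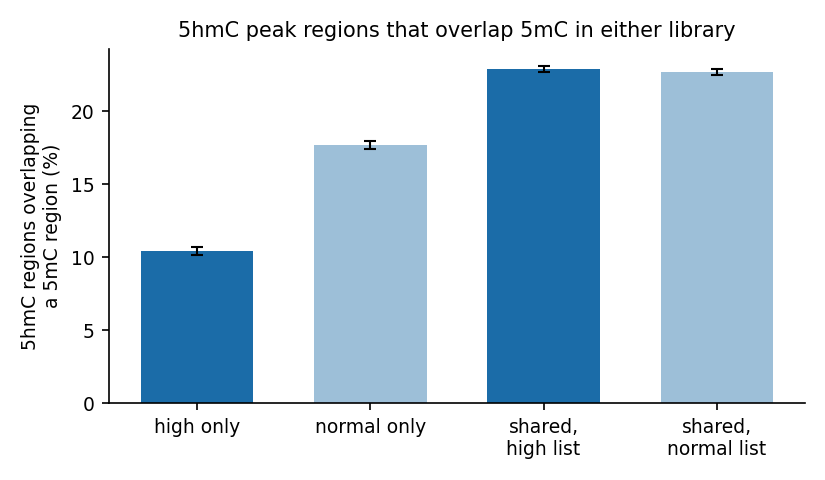
Percent of 5hmC peak regions that overlap a 5mC region of either 5mC list (vertical axis) for regions found in high glucose alone, in normal glucose alone and at both levels (horizontal axis), 1 library per group, with Wilson 95% intervals that cover counting only. Regions of high glucose alone lie at 10.4%, those of normal glucose alone at 17.7% and shared regions at 22.9% and 22.7%. No random placement was made for these shares.

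Places where the marks differed in opposite ways between the glucose levels were counted next, since TET2 turns 5mC into 5hmC. Of the 5hmC regions found in normal glucose alone, 1472 overlapped a 5mC region found in high glucose alone, where random placement gave a mean of 592, and 915 within the same 1 Mb window. The converse, 5hmC in high glucose alone with 5mC in normal glucose alone, held for 475 regions, where random placement gave 276, and 362 within the same window. Pairs that went the same way were found at 953 places in high glucose alone and 1541 in normal glucose alone, against 395 and 411 by random placement and 506 and 645 within the same window. From the totals of each kind, 1645 pairs of the first kind and 648 of the converse would be found if the marks varied independently, so opposite pairs were fewer than independence gives. The odds ratio of same-way over opposite pairs was 2.10. Across the 2875 windows, which are not independent, the high-minus-normal differences in cover of the marks correlated at a Spearman rho of -0.345 and a Pearson r of -0.522. With the totals of each mark made equal between the glucose levels, a setting added after the data were seen, these were 0.00692 and 0.217. The input read numbers worked out from the lists were alike for both marks, 33.7 M in high and 29.3 M in normal glucose, and if 1 input served both marks, their regions are not independent. With every list cut at a -log10 p of at least 10, the count of normal-only 5hmC with high-only 5mC was 480. With the same number of top peaks from each library this count was 961.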

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

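The tests of read depth, weak peaks and matched background in this part were chosen after the results were seen, and the ratios they use were known when their bounds were set. At the threshold of the lists, the marks differed in opposite directions between the glucose levels. The ratio of peak region numbers, high over normal glucose, was 0.911 for 5hmC and 1.09 for 5mC, each from 1 library against 1, and the difference between the marks was not tested. At a -log10 p of at least 10 the opposition was lost, with 1.12 for 5hmC and 1.097 for 5mC as deposited and 0.941 and 0.953 with matched background.

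For 5hmC, the tables argue against lower read depth as the cause of the lower number, because the high-glucose library had 1.02 times the reads of the normal-glucose library. Weak peaks near the calling threshold as the cause cannot be told apart from a wider difference. The background-matched ratio was 1.06 at a -log10 p of at least 20 but 0.941 at 10. At the threshold of the lists it was 0.907, but there the scaling left 190402 of 191314 high-glucose regions and so could hardly move it. For 5mC, the high-glucose library had 1.203 times the reads. The background-matched ratio was 1.09 at the threshold of the lists, where the scaling left 99717 of 100220 regions and so could hardly move it. That value does not speak against depth. At a -log10 p of at least 7, 10, 15 and 20, where the scaling removed more regions, the ratio was 0.966, 0.953, 0.955 and 0.962. Depth as the cause of the higher number cannot be told apart from a difference between the cultures. An effect of glucose stays open for both marks and was not tested beyond these libraries.

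Peaks were also listed outside the chromosomes compared, and they are given as values only, since no list of the input libraries was used here to set a control level. Mitochondrial DNA held 6 peaks in the high-glucose 5hmC list, 4 in the high-glucose 5mC list and 6 in the normal-glucose 5mC list, and 2 in the normal-glucose 5hmC list. The Y chromosome held 74 and 80 peaks in the high- and normal-glucose 5hmC lists and 10 and 9 in the 5mC lists.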

How the results depend on the processing

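The alternatives with a -log10 p of at least 10 or with matched background were chosen after the data, and other thresholds, were seen. The lower number of 5hmC regions in high glucose held under 7 of 8 alternatives: the ratio was 0.925 at a -log10 q of at least 2, 0.924 with rows within 500 bp merged, 0.922 by covered length and 0.941 with matched background and a -log10 p of at least 10, but it reversed to 1.12 at a -log10 p of at least 10 without matched background. The higher number of 5mC regions held under 7 of 8: it was 1.08 by covered length and reversed to 0.953 with matched background and a -log10 p of at least 10. Matched background at the threshold of the lists is among the alternatives that held for both marks. It left 190402 of 191314 high-glucose 5hmC and 99717 of 100220 high-glucose 5mC regions, so it could hardly move either ratio. Across thresholds the reversals were wider than these tallies show: at a -log10 p of at least 7, 10, 15 and 20 the deposited 5hmC ratio was 1.04, 1.12, 1.25 and 1.39, and the 5mC ratio with matched background 0.966, 0.953, 0.955 and 0.962. The cause of either reversal was not tested, and matching the 5hmC background is mostly a correction for fragment length, since the backgrounds differed by 1.15 times and the reads by 1.02 times. The share of high-glucose 5hmC regions found in normal glucose was 75.7% at a -log10 p of at least 3 and 75.2% at a -log10 q of at least 2. It was 63.0% with 50% of both regions and 72.5% with equal numbers of top peaks. With both lists cut at a -log10 p of at least 10 it was 64.7%, and 70.4% with matched background. Against the full normal-glucose list, 9435 of the 95542 high-glucose regions at that threshold had no partner. The share of normal-glucose 5hmC regions found in high glucose was 72.2% with both lists cut at 10, so the order of the shares turned there. With matched background it was 66.1%. For 5mC the share of high-glucose regions found in normal glucose was 62.5% with 50% of both regions and 75.3% with equal numbers of top peaks. At a -log10 p of at least 10 it was 75.2%, and 81.2% with matched background. The share of normal-glucose 5mC regions found in high glucose was 82.5% and 77.6% in these settings, so the order turned with matched background. The lower share of 5mC regions with 5hmC in high glucose kept its direction under all 9 alternatives, with -3.15 percentage points for 50% of both regions, -3.54 for equal numbers of top peaks, -3.33 at a -log10 p of at least 10 and -4.96 with matched background at that threshold. The count of normal-only 5hmC with high-only 5mC was 961 with equal numbers of top peaks, 480 at a -log10 p of at least 10 and 377 with matched background at that threshold. The odds ratio of same-way over opposite pairs ranged from 1.55 to 2.24. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. The alternatives for gene parts, gene lists and named genes were not run, because no annotation on hg19 was used here. The 5mC lists, from 6.14 M and 5.11 M reads, limit the detection of weak 5mC regions more than the 5hmC lists do.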

Other observations

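The descriptions in this part were chosen after the data were seen, as were the tests of fragment length and of a shared input, while the tests of an input difference, of weak peaks and of 5mC density were set before their results. The 5mC regions gathered near chromosome ends. Within 5 Mb of the outermost listed peaks of each chromosome, which is 7.81% of the span, lay 21.97% of high-glucose and 22.6% of normal-glucose 5mC regions, against 13.5% and 13.9% of 5hmC regions. The 10 widest 5mC regions of each list lay in these end zones, among them a region of 16.6 kb on chromosome 16 from 586164 to 602803 in high glucose, whose normal-glucose counterpart was 16.9 kb wide. Of the 10 widest 5hmC regions in each list, 8 lay within 5 Mb of the longest stretch of their chromosome without any peak. In each list 4 of the 10 lay in the end zones, so some lay in both. The widest, on chromosome 21 from 10773646 to 10829517 in high glucose, was 55.9 kb wide in both 5hmC lists. Across the 1 Mb windows, which are not independent, 5hmC and 5mC cover correlated with a Spearman rho of 0.802 in high and 0.845 in normal glucose.

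The lower 5hmC number in high glucose was graded by 5mC density, a pattern noticed in the data and examined on the same data. With the 2875 windows split into 5 equal groups by their mean 5mC cover, the ratio of 5hmC regions, high over normal glucose, was 1.04, 0.983, 0.940, 0.897 and 0.868 from the poorest to the richest group. With only peaks of -log10 p of at least 10 it was above 1 in each group, and 1.02 in the richest, which was 0.787 times the ratio of the poorest. 5hmC cover was lower in high glucose in 22.8% of the windows of the poorest and 92.5% of the richest group. The groups also differed in 5hmC density. From the poorest to the richest, mean 5hmC cover rose from 1.38% to 9.18% in high and from 1.22% to 10.8% in normal glucose. A gradient by 5mC density thus cannot be told apart from one by 5hmC density. The ratio of the richest over the poorest group was 0.832 over all windows, 0.836 in regions at least 5 Mb from the chromosome ends and below 1 on 23 of 23 chromosomes. A gradient of the same direction was present for 5mC regions, with a ratio of the richest over the poorest group of 0.860 over all peaks, 0.864 with matched background and 0.922 at a -log10 p of at least 10, though 1.03 with both together. Across windows the high-minus-normal difference in cover correlated with mean 5mC cover at a Spearman rho of -0.605 for 5hmC and 0.495 for 5mC, and at -0.378 and -0.0768 with the totals of each mark made equal.

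Peaks with a -log10 p under 10 as the only cause are argued against by the contrast at the stricter threshold. With matched background and a -log10 p of at least 10, the ratio of the richest over the poorest group was 0.836. Regions near that stricter threshold can still drop out of 1 list, so the value cannot decide on peaks near a threshold in general. A difference between the inputs stays open: the expected counts in the 5hmC lists rose 1.03 times as much from the poorest to the richest group in high as in normal glucose, under the bound set beforehand, but that bound was wrong because expected counts exist only where a peak was called. The 5mC lists, looked at after that value was seen, gave 1.07 (0.967 to 1.15 over chromosomes drawn with replacement), and raising the normal-glucose expected counts by 1.15 times moved the ratio of the richest over the poorest group from 0.832 to 0.848, but these values too come from called peaks. GC content and fragment length cannot be told apart from an effect of glucose, since the fragment lengths read from the 5hmC lists differed by 33 bp and no hg19 sequence was used here. A loss of 5hmC in high glucose where 5mC, and with it 5hmC, is dense stays a hypothesis from 1 library per group.

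Regions found at 1 glucose level tended to go the same way in both marks, with an odds ratio of 2.10. Different 5mC density between the 5 groups of windows is argued against by an odds ratio of 2.10 after stratifying by them (Mantel-Haenszel). From the poorest to the richest group the odds ratios were uneven, at 6.07, 3.45, 2.13, 1.70 and 2.18. The richest group spanned 3.29% to 40.9% 5mC cover. Density differences within a group, or within a 1 Mb window, thus stay open. The input read numbers worked out from the 5hmC and the 5mC list of a glucose level differed by at most 8.91e-05%, so both marks were probably called against the same input library, whose chance lows would favour peaks of both marks. The odds ratio was 1.78 with every list of both marks cut at a -log10 p of at least 10. A shared input as the cause cannot be told apart from places that gained both marks, because the input reads were not analysed here. No biological explanation was tested.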
